A study of Mus musculus with 10 samples.

How the data were processed

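Gene expression was measured by RNA sequencing in whole lung tissue of ICR mice aged 7 to 9 weeks, with 5 libraries from ventilated animals (VILI, ventilator-induced lung injury) and 5 from controls. Per the labels' protocols, the VILI animals were ventilated at a tidal volume of 30 ml/kg and 70 breaths/min for 4 h, and the sham animals were intubated and left to breathe on their own. RNA was extracted with Trizol and sequenced on the Ion Proton platform, per the labels' protocols. The deposited table holds whole-number read counts per gene and library, not normalised, as the values show. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner, the counting tool, its strand setting and the annotation version were not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The labels do not state in so many words that each library came from a separate animal, so p-values measure the spread between these libraries.

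The table listed 44788 names. One entry without a gene name held 0 counts and was left out, and 44787 names were used. Names were matched to the RefSeq gene table of GRCm38.p6, by current symbol for 32095 names, by gene identifier for 5761 and by synonym for 1754. The 5177 names without a match carried 0.306% of all counts. The match gave 21377 protein-coding genes and 7369 lncRNA (long non-coding RNA) genes. Coordinates are 1-based positions on GRCm38. Gene names are printed as deposited, with a current symbol where that helps. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and counts of near-identical copies are uncertain.

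Library totals ranged from 14646592 to 36393132 counts. Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, filterByExpr (minimum count 10, minimum total 15) and the robust quasi-likelihood F test with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold change over 2, the thresholds named in the series' design. Adjusted p-values of genes are from this edgeR test unless another tool is named. Levels are TMM-normalised CPM (the count per 1e6 counts of a library), given as mean ± SD over 5 libraries, and log2 fold changes carry the standard error (SE). Sums of marker genes use CPM without TMM factors. Counts were simulated for the comparison of 5 against 5 libraries, over 18593 genes. The test gave back 84.5% of genes changed by 1.5 on the log2 scale and 100% of those changed by 3, with 4 false calls. Simulated for replicates 1 to 3 alone, it gave back 70.4% and 100%, with 3 false calls. For replicates 4 and 5 alone it gave back 47.8% and 90.3%, with 2 false calls. Each gene was drawn independently, and simulated libraries differed only by group and library size. These rates need not hold for the real libraries. All pairs of libraries of one group differed by more than counting noise, with a chi-square of at least 14.11 per gene, so none was treated as a duplicate. The common biological coefficient of variation was 26.5%.

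A total of 42 gene lists with at least 4 tested members were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list move, on balance, in one direction and does not compare them with other genes. Members of a list were counted as risen or fallen at an adjusted p under 0.05 of the edgeR test with no fold minimum. The nearest protein-coding gene within 100 kb of each lncRNA was taken from the RefSeq table, and the share called was compared by a two-sided Fisher's exact test. Strands for the closing section came from GENCODE M21.

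Lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 called protein-coding genes with the largest and the 10 with the smallest log2 fold change, and 5 and 5 lncRNAs, among genes with a mean of at least 1 CPM and no overlap between the groups' ranges. In each list it took up to 4 members past the threshold with the largest absolute change. Where no member passed, it took the 2 with the highest CPM. Some genes that the rule took are not reported here. Genes outside the rule are said to be chosen after their values were seen. The alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE and upper-quartile scaling, no filter, a filter of 10 counts in 5 libraries, the replicate number as a block, no fold minimum and leaving out each library. The library totals showed a split that the labels do not name: replicates 1 to 3 held 29317070 to 36393132 counts and replicates 4 and 5 held 14646592 to 17009435 in both groups. Fits within each of these depth sets, and a fit with the set as a covariate, were added after seeing the data. Another 8 gene lists, reported only in the closing section, were also added then.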

Results

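The series asked which protein-coding genes and lncRNAs change in the mouse lung under injurious mechanical ventilation. Read counts were available for 5 VILI lungs, ventilated at 30 ml/kg for 4 h, and 5 control lungs. Library totals were 30954683, 29317070, 32087361, 16496073 and 17009435 counts for control replicates 1 to 5, and 36393132, 31619667, 30926411, 14815545 and 14646592 counts for VILI replicates 1 to 5. Between 24427 and 27114 genes had at least 1 count in a library.

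In VILI lungs, all 11 antioxidant genes, 16 of 22 immediate early genes and 11 of 12 glucocorticoid-responsive genes on the lists rose, and 7 of 12 B cell markers and 9 of 14 cell division genes fell. Of these lists only the antioxidant one kept its camera call with an estimated correlation. Among protein-coding genes that met the naming rule, the largest increase was in Fosl1, a subunit of the AP-1 transcription factor. It rose from 0.0593 ± 0.0582 CPM in controls to 36.9 ± 8.03 in VILI (SD, n = 5; log2 fold change 9.12, SE 0.385, adjusted p = 1.33e-07). It was followed by Slc7a11, the cystine transporter, which rose from 1.42 ± 0.581 to 200.8 ± 21.2 CPM (log2 7.21, SE 0.253, adjusted p = 2.99e-08). Hmox1, the haem-degrading enzyme, was the most abundant of the 10 leading genes and rose 43.9-fold, from 35.8 ± 6.12 to 1568 ± 331.2 CPM (adjusted p = 2.99e-08). The remaining leading genes were the serine protease Prss22 (log2 6.61), the peptide hormone Adm2 (6.60), the decoy receptor Il1r2 (6.42), the itaconate-producing enzyme Irg1, now Acod1 (6.22), Tarm1 (6.09), the stress cytokine Gdf15 (5.76) and the tight junction gene Cldn4 (4.89). Their adjusted p-values lay between 1.27e-06 for Prss22 and 0.00187 for Irg1.

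By the same rule the largest decrease was in Uts2r, the urotensin receptor, from 3.95 ± 2.28 to 0.181 ± 0.133 CPM (SD, n = 5; log2 -4.33, SE 0.509, adjusted p = 0.000184). Cx3cr1, the fractalkine receptor of monocytes and macrophages, decreased by 3.01 on the log2 scale, from 13.5 ± 3.79 to 1.61 ± 0.963 CPM (adjusted p = 0.000409). Adrb3, the beta-3 adrenergic receptor, fell by 2.91 on the log2 scale (SE 0.269, adjusted p = 3.6e-05), and Cr2, a complement receptor of B cells, fell by 2.77 (adjusted p = 0.00117). Rbbp8nl, Rmi2, Shisa2, Dclk3, Zfp750 and Fam198a completed the 10 leading decreases, with log2 fold changes from -3.41 for Rbbp8nl to -2.56 for Fam198a. The ranges of the groups did not overlap for any of these 20 genes, as the naming rule required. Called genes with overlapping ranges were left out of this ranking, among them Mmp8 (log2 5.70).

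**Figure D1:**
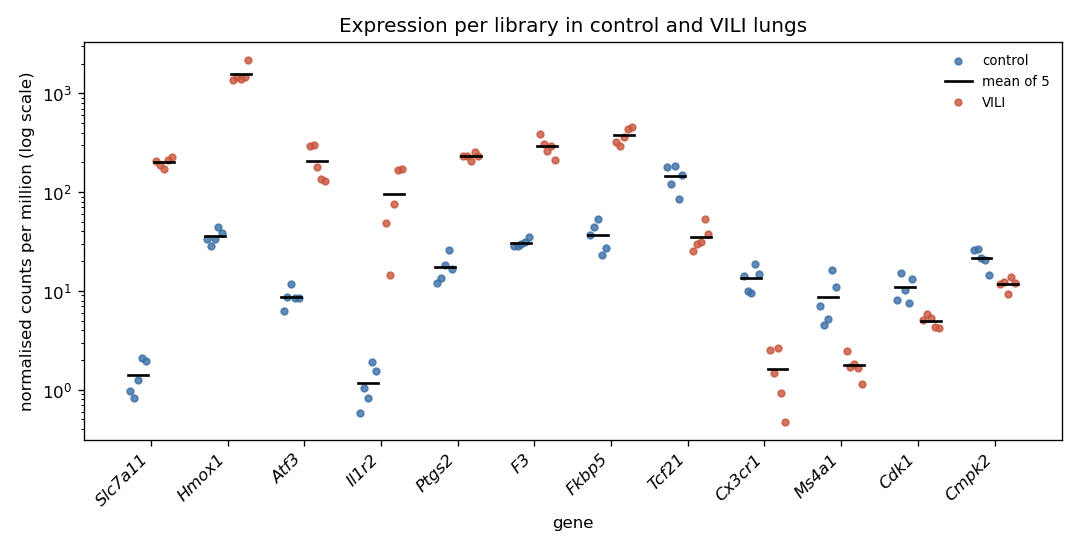
Normalised CPM (log axis) of 12 genes in each control (blue) and VILI (red) library, with black bars at the mean of 5. Hmox1 had a mean of 35.8 CPM in controls and 1568 CPM in VILI, and Cx3cr1 had 13.5 and 1.61 CPM.

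Of 18874 genes tested, 714 were higher and 518 lower in VILI at an adjusted p under 0.05 and over 2-fold (edgeR). With no fold minimum the counts were 2233 and 1961. In 3312 genes, or 17.55%, the ranges of the groups did not overlap. The average over all splits of 10 libraries into 5 and 5 is 0.794% without ties. A single split of libraries that share structure can lie above this average, and the share was not computed for other splits. Protein-coding genes made up 593 of the higher and 405 of the lower genes, out of 14959 tested. Within replicates 1 to 3 the counts were 945 higher and 671 lower, and within replicates 4 and 5 they were 678 and 453. Of the 1137 called genes tested in both sets, 1136 had the same sign in both and 736 were over 2-fold in both, among genes selected on the same libraries. Upper-quartile scaling called 600 genes higher and 694 lower, so the balance of directions depended on the scaling. Without control replicate 5, which held germ cell transcripts, 771 genes were higher and 503 lower.

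All 11 members of the antioxidant list of NRF2 targets and metallothioneins rose, and all 11 also passed adjusted over the list alone. Gclc, which makes the rate-limiting subunit of glutathione synthesis, rose from 96.7 ± 21 to 1452 ± 280.2 CPM (SD, n = 5; log2 3.91, SE 0.196, adjusted p = 4.2e-07). Srxn1, sulfiredoxin, rose 13.7-fold (adjusted p = 2.99e-08), beside Slc7a11 and Hmox1. The list's median log2 fold change was 3.52, and camera placed it above all other genes (adjusted p = 3.07e-17). This was the only list whose call was kept with an estimated correlation (adjusted p = 0.00128 with an estimated correlation).

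Of 22 immediate early genes, 16 rose and none fell, with 18 risen adjusted over the list alone. Atf3, a stress-induced transcription factor, rose 23.7-fold to 208.5 ± 84.6 CPM and Maff 13-fold to 181.8 ± 51.9 CPM (SD, n = 5; adjusted p = 4.79e-06 and 2.67e-06). Camera called the list (adjusted p = 4.68e-13), but not with an estimated correlation (adjusted p = 0.175 with an estimated correlation). The list of the unfolded protein and amino acid stress response had 10 members that rose and 1 that fell out of 15, or 11 and 1 adjusted over the list alone. Its leading genes were the kinase-like regulator Trib3 (log2 2.83, SE 0.118), Sesn2 (2.52, SE 0.12) and the glutathione-degrading enzyme Chac1 (2.44, SE 0.148), at adjusted p-values of 1.28e-07, 3.75e-07 and 1.68e-06. By camera this list had adjusted p = 5.16e-07, and adjusted p = 0.175 with an estimated correlation. In the glucocorticoid response list 11 of 12 members rose, or 12 adjusted over the list alone. The co-chaperone Fkbp5 rose 10.1-fold to 375.2 ± 73.7 CPM, Pdk4 rose 9.54-fold and Zbtb16 rose 6.39-fold (adjusted p = 7.46e-06, 4.92e-05 and 0.00102). This list had adjusted p = 1.58e-11 by camera and adjusted p = 0.14 with an estimated correlation.

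Hypoxia and glycolysis genes rose in 7 of 13 cases, 8 adjusted over the list alone, led by the glucose transporter Slc2a1 (log2 2.07, SE 0.102, adjusted p = 4.07e-07) and hexokinase Hk2 (1.99, SE 0.151, adjusted p = 9.16e-06). The list had adjusted p = 0.000172 by camera, and adjusted p = 0.0519 with an estimated correlation. Heat shock chaperones rose in 7 of 13 cases, 9 adjusted over the list alone, but unevenly between libraries. Hspa1a, whose reads are uncertain because Hspa1b is a near-identical copy, stood at 8.74 and 7.62 CPM in VILI replicates 1 and 2 and at 139.3, 343 and 861 CPM in VILI replicates 3 to 5, against 3.33 to 11.9 CPM in controls, before TMM factors. Its log2 fold change was 5.36 (SE 1.21, adjusted p = 0.00983), and its call was lost within replicates 1 to 3 (adjusted p = 0.176), with the replicate number as a block (adjusted p = 0.132) and with limma-voom. The chaperone list had adjusted p = 0.00529 by camera and adjusted p = 0.632 with an estimated correlation. Fry, against no change, gave adjusted p = 0.118, and within replicates 1 to 3 camera gave adjusted p = 0.55.

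Among inflammatory genes, Ptgs2, the inducible cyclooxygenase, rose from 17.4 ± 5.54 to 233.2 ± 17.1 CPM (SD, n = 5; log2 3.75, SE 0.198, adjusted p = 5.81e-07). The cytokine Osm rose 7.81-fold (adjusted p = 0.00309). In the list of cytokines and lipid mediators 4 members rose and 1 fell out of 14, the same counts adjusted over the list alone, and camera, against other genes, made no call (adjusted p = 0.211), while fry, against no change, gave adjusted p = 0.0168. With no low-count filter camera called this list (adjusted p = 0.0171). The neutrophil chemoattractants Cxcl2 and Cxcl1 rose by log2 3.54 (SE 0.518) and 2.27 (SE 0.272), at adjusted p-values of 0.000772 and 0.000212, from below 1 CPM in controls. They were 2 of 4 members tested, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.0742), while fry, against no change, gave adjusted p = 0.000702. Camera called it under upper-quartile scaling (adjusted p = 0.0398) and with no low-count filter (adjusted p = 0.0104). NF-kB feedback genes rose in 9 and fell in 1 of 15 cases, also adjusted over the list alone, with Bcl3 3.68-fold and Birc3 2.52-fold higher (adjusted p = 0.000145 and 4.46e-05). The NF-kB list had adjusted p = 0.000161 by camera, and adjusted p = 0.261 with an estimated correlation. Acute phase and epithelial defence genes rose in 6 of 13 cases, or 8 risen and 1 fallen adjusted over the list alone. Socs3, a brake on cytokine signalling, rose 5.52-fold and Serpina3n, from a family of close copies, 7.86-fold (adjusted p = 5.24e-06 and 2.5e-05). That list had adjusted p = 0.000458 by camera and adjusted p = 0.261 with an estimated correlation.

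Neutrophil markers rose in 13 and fell in 1 of 16 cases, or 14 and 1 adjusted over the list alone. The decoy receptor Il1r2 rose from 1.18 ± 0.535 to 95.8 ± 71 CPM, Clec4d from 2.57 ± 1.56 to 45.9 ± 34.3 and Retnlg from 10.1 ± 8.42 to 166.5 ± 119.5 (SD, n = 5; adjusted p = 0.000176, 0.0015 and 0.00476). The spread within VILI was wide, and Il1r2 lay at 14.59 CPM in VILI replicate 2 and at 172.9 CPM in VILI replicate 5. The controls also parted, with a mean centred log2 CPM of the list of -0.611 and -0.798 in control replicates 4 and 5 and of -2.188 to -1.86 in control replicates 1 to 3. VILI replicate 2 stood at -0.348 and the other VILI libraries at 1.103 to 2.402. Camera called the list (adjusted p = 3.67e-07), but not with an estimated correlation (adjusted p = 0.275 with an estimated correlation). Alveolar macrophage markers did not follow the groups. Chil3, with an adjusted p of 0.69, and the other 12 markers of that list summed to 78.79 to 106.5 CPM in control replicates 1 to 3 and VILI replicates 1 and 2, and to 931.8 to 1273 CPM in control replicates 4 and 5 and VILI replicates 3 to 5.

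Genes of coagulation and fibrinolysis rose in 5 and fell in 1 of 12 cases, also adjusted over the list alone. F3, tissue factor, rose from 30.6 ± 2.86 to 292.1 ± 65.9 CPM (SD, n = 5; log2 3.26, SE 0.159, adjusted p = 4.05e-07). Plaur, the urokinase receptor, rose 6.81-fold (adjusted p = 1.32e-05). Camera gave adjusted p = 0.016 for the list, and adjusted p = 0.261 with an estimated correlation. Genes of epithelial junctions and fluid transport rose in 9 of 17 cases, or 11 adjusted over the list alone. Cldn4 rose 29.7-fold, the sodium pump subunit Atp1b1 2.31-fold and Cdh1, E-cadherin, 1.72-fold (adjusted p = 2.96e-05, 0.000134 and 0.0013). This list had adjusted p = 5.44e-05 by camera and adjusted p = 0.261 with an estimated correlation. Of 13 YAP and stretch response genes, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone. Camera made no call for them (adjusted p = 0.336). The list's mean centred log2 CPM was 0.568 to 1.007 in VILI replicates 1 to 3. In VILI replicates 4 and 5 it was -0.076 and -0.382, and in controls -0.542 to -0.147. The growth factor Areg rose 22.1-fold and Thbs1, thrombospondin, 7.01-fold (adjusted p = 0.000425 and 0.000114). Among 16 matrix remodelling genes 5 rose and 2 fell, also adjusted over the list alone, including Lox, which cross-links collagen (log2 2.56, SE 0.346, adjusted p = 0.000572), and the hyaluronan synthase Has1 (2.05, SE 0.252, adjusted p = 0.000254). Camera did not call the matrix list (adjusted p = 0.192), but did without VILI replicate 5 (adjusted p = 0.0441).

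B cell markers fell in 7 of 12 cases, or 9 adjusted over the list alone. Fcer2a fell from 14.2 ± 9.51 to 2.55 ± 0.714 CPM and Ms4a1, the CD20 antigen, from 8.76 ± 4.8 to 1.76 ± 0.467 CPM (SD, n = 5; adjusted p = 0.00269 and 0.00123). The B cell list had adjusted p = 0.000165 by camera, and adjusted p = 0.553 with an estimated correlation. The mean level of these markers was higher in control replicates 4 and 5 than in the other controls, and within replicates 1 to 3 the list's mean log2 fold change was -0.54 with adjusted p = 0.0506. Cell division genes fell in 9 of 14 cases, or 13 adjusted over the list alone. Cdk1 fell by 1.12 (SE 0.206) and Top2a by 1.01 (SE 0.183) on the log2 scale (adjusted p = 0.00295 and 0.00275). Top2a did not pass within replicates 4 and 5 (adjusted p = 0.0955). Across 20 alternatives its log2 fold change lay between -1.117 and -0.898. This list had adjusted p = 2.46e-06 by camera and adjusted p = 0.261 with an estimated correlation. Type I interferon response genes fell in 6 of 16 cases, or 7 adjusted over the list alone. Cmpk2 and Gbp2 had log2 fold changes of -0.88 and -0.70 (adjusted p = 0.004 and 0.0079). Neither gene passed within replicates 4 and 5 (adjusted p = 0.21 and 0.147). The interferon list had adjusted p = 0.00547 by camera, and adjusted p = 0.494 with an estimated correlation. Within replicates 4 and 5 its adjusted p was 0.18.

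Ciliated airway markers had 2 members that fell out of 14, also adjusted over the list alone, the dynein genes Dnah5 and Dnah9 (log2 -0.67 and -0.54, adjusted p = 0.00939 and 0.0189). Both changes were under 2-fold. Dnah5 did not pass an adjusted p of 0.05 within replicates 1 to 3 (adjusted p = 0.0591), nor Dnah9 within replicates 4 and 5 (adjusted p = 0.143). The list's mean centred log2 CPM was 0.598 in control replicate 2 and -0.66 in VILI replicate 3, the ends of its range, and those of the secretory airway list (0.706 and -0.9) and the mesothelium list (0.442 and -0.598) lay in the same libraries. Camera called that list (adjusted p = 0.00226), but not with an estimated correlation (adjusted p = 0.632 with an estimated correlation), and fry, against no change, gave adjusted p = 0.0611. Single genes changed in other cell type lists that camera did not call. Tcf21, a transcription factor of lung fibroblasts, fell from 144.2 ± 41.9 to 35.6 ± 11 CPM and Inmt from 2865 ± 265.9 to 2036 ± 134 CPM (SD, n = 5; adjusted p = 0.00028 and 0.0108), with 4 of 13 fibroblast markers fallen. Tcf21 lost its call within replicates 4 and 5 (log2 -1.367, adjusted p = 0.0867). The VEGF receptor Kdr had a log2 fold change of -0.74 (adjusted p = 0.00233), and endothelial markers went both ways, with 2 risen and 3 fallen of 15. Gabrp of secretory airway cells fell by 1.35, the NK cell receptor Ncr1 fell by 2.21, and Krt19 rose by 1.22 on the log2 scale (adjusted p = 0.00117, 0.0036 and 0.000108). Gabrp was the only secretory airway marker of 12 past the threshold, and Ncr1 the only NK cell marker of 10. Among T cell markers Il7r rose (log2 1.19, adjusted p = 0.00768), with 2 risen and 3 fallen of 14. The alveolar type 1 marker Hopx rose by 0.55 on the log2 scale (adjusted p = 0.00446), as 1 of 2 risen markers out of 11. Camera did not call the secretory airway list (adjusted p = 0.099), but did without control replicate 1 (adjusted p = 0.0192) or VILI replicate 2 (adjusted p = 0.0267). Alveolar type 2 markers, with 1 of 12 risen, and red cell markers were also not called (adjusted p = 0.192 and 0.23). The former were called without control replicate 4 (adjusted p = 0.0192), and the latter without control replicate 3 (adjusted p = 0.0324). The lists without a camera call also included monocyte and lymphocyte chemokines (2 risen of 10), endothelial adhesion (1 risen and 1 fallen of 12), circadian clock output (1 and 1 of 13), monocytes (1 risen of 10), mesothelium (1 risen and 3 fallen of 7), adipose tissue (2 fallen of 7), thymus and thyroid (2 risen and 1 fallen of 4, with adjusted p = 2.46e-05 by fry, against no change) and sex-linked genes (1 risen of 4). Adjusted over the list alone, the alveolar type 2 and monocyte lists had 0 risen members and the circadian list 0 fallen. No marker passed the threshold in the lists of smooth muscle, alveolar macrophages, platelets, red cells, cardiac muscle, skeletal muscle or mitochondrial mRNAs.

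**Figure D2:**
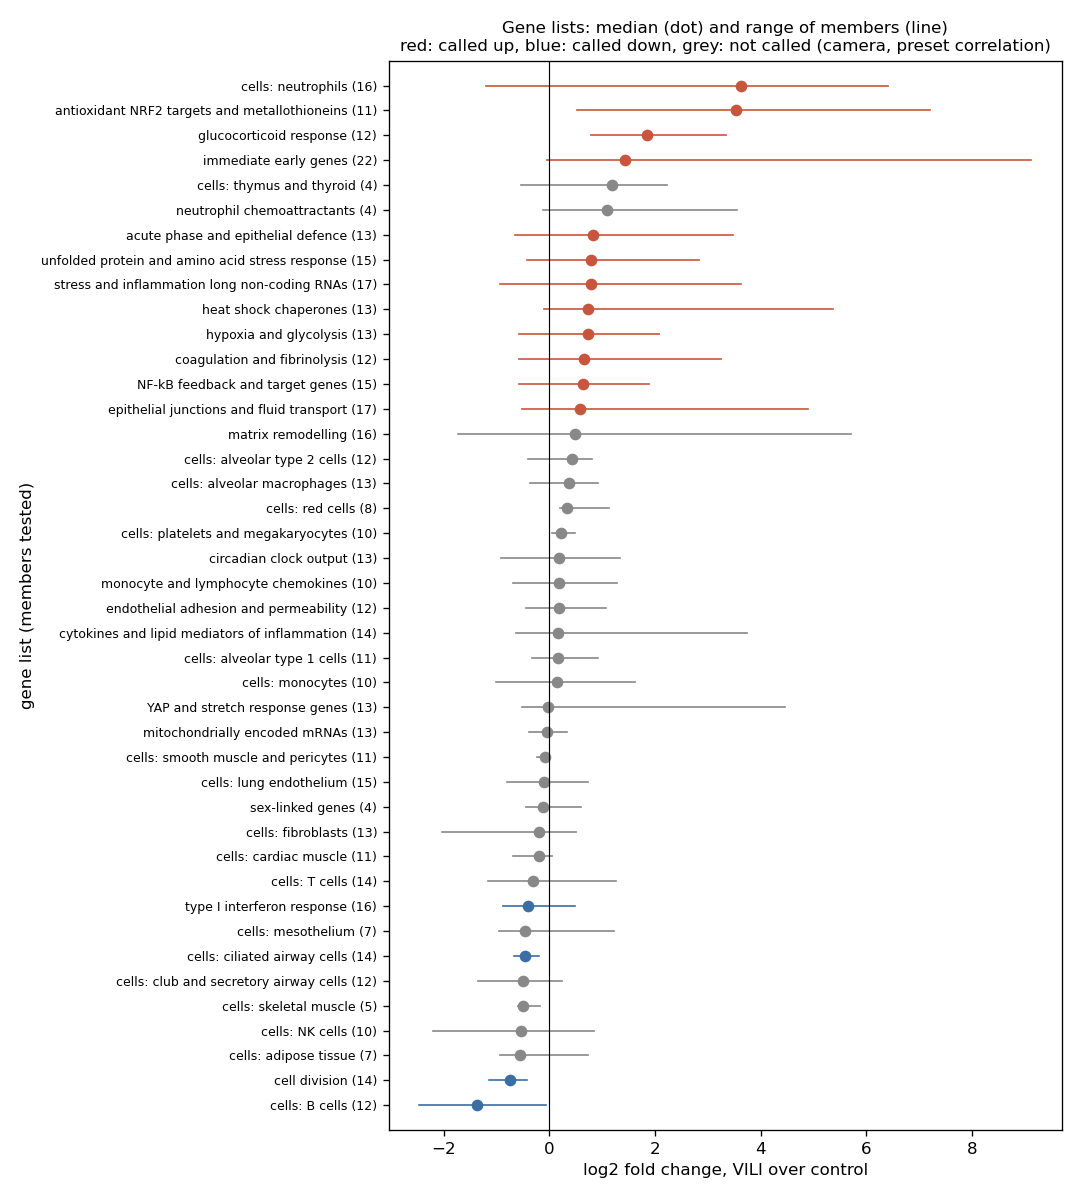
Median log2 fold change of VILI over control (dots) and the range of the members (lines) for 42 gene lists, with the number of tested members in brackets. Red and blue mark lists called up (12) and down (4) by camera with a preset correlation, and grey marks lists without a call.

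**Figure D3:**
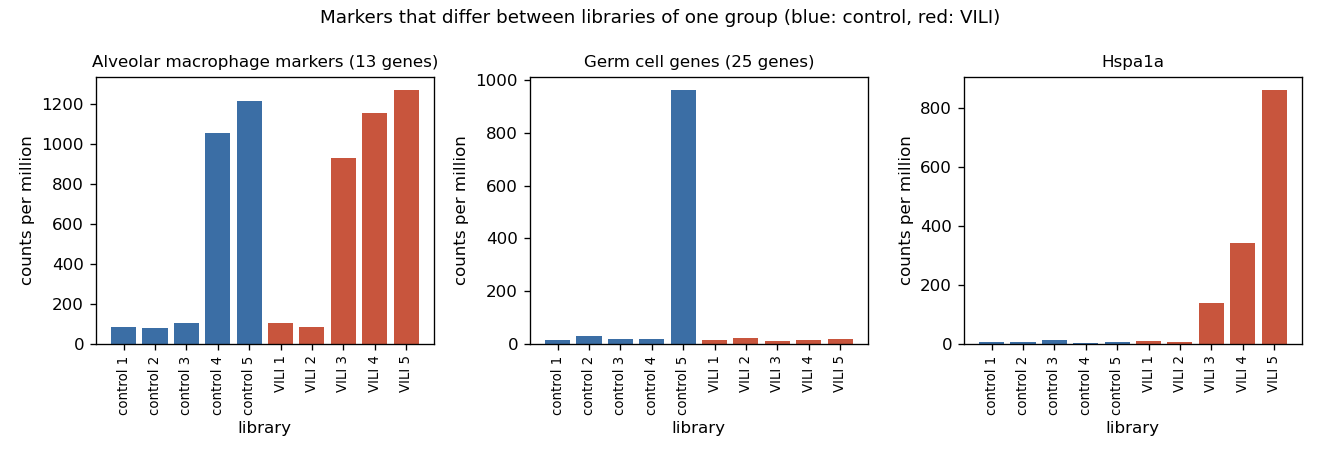
CPM in each library, summed over 13 alveolar macrophage markers (left) and 25 germ cell genes (middle), and of Hspa1a (right), with controls in blue and VILI in red. The macrophage markers lay between 931.8 and 1273 CPM in 5 libraries and between 78.79 and 106.5 CPM in the other 5, and the germ cell genes stood at 962.5 CPM in control replicate 5.

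Among lncRNAs that met the naming rule, the largest increase was in Gm4610 (chromosome 3, 122377097 to 122391996), from 0.443 ± 0.0941 to 7.18 ± 0.884 CPM (SD, n = 5; log2 4.02, SE 0.194, adjusted p = 3.76e-07). LOC102640883 (chromosome 5, 116406680 to 116418761) rose by 3.96 on the log2 scale, Gm11827 (chromosome 4, 11123958 to 11126998) by 3.68, Gm10872 (Mirt2, chromosome 15, 76266787 to 76269839) by 3.62 and A730049H05Rik (chromosome 6, 92816443 to 92843468) by 3.46. Their adjusted p-values were 0.00027, 2.37e-06, 0.000764 and 0.000548. By the same rule the largest decrease was in Gm10824 (chromosome 10, 22813381 to 22821942), from 2.06 ± 0.374 to 0.366 ± 0.0904 CPM (log2 -2.46, SE 0.251, adjusted p = 6.88e-05). Gm10824 overlaps Tcf21, LOC102640883 overlaps Hspb8, A730049H05Rik overlaps Adamts9 and 5730596B20Rik, below, overlaps Hoxa3, and the reads of each pair cannot be told apart without strand. LOC102632993 (chromosome 7), 9630028I04Rik (chromosome 17), 5730596B20Rik (chromosome 6) and AI197445 (chromosome 13) fell by 1.82, 1.78, 1.78 and 1.66 on the log2 scale (adjusted p = 0.000125, 0.00082, 0.00262 and 0.00135). In the list of stress and inflammation lncRNAs 9 of 17 rose, also adjusted over the list alone, including LOC102639566 (Ptgs2os2, log2 1.89, adjusted p = 0.000628) and Gm11974 (Snhg15, log2 1.44, adjusted p = 0.00263). That list had adjusted p = 0.0012 by camera and adjusted p = 0.261 with an estimated correlation.

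Of 907 lncRNA genes tested, 52 were higher and 64 lower in VILI, or 51 and 62 adjusted over lncRNAs alone. LncRNAs had a median of 1.05 CPM against 23.6 CPM for protein-coding genes. Within replicates 1 to 3 the counts were 61 and 83, and within replicates 4 and 5 they were 33 and 30. Upper-quartile scaling gave 45 and 81.

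Called lncRNAs lay beside called protein-coding genes more often than other lncRNAs did. Gm4610 lies 27761 bp from Bcar3, Gm11827 29443 bp from Trp53inp1 and LOC102639566 50809 bp from Ptgs2, and each pair rose together. Of 113 called lncRNAs with a tested neighbour within 100 kb, 22 (19.5%) had a called neighbour, against 54 of 750 (7.2%) of the other lncRNAs (odds ratio 3.11, 95% interval 1.72 to 5.48, two-sided Fisher's exact test p = 0.000109). The pairs changed in the same direction in 20 of 22 cases, and 10 pairs overlapped in the genome. Within replicates 1 to 3 the odds ratio was 1.51 (Fisher's exact test p = 0.183), so the association was not past the threshold there, and within replicates 4 and 5 it was 3.55.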

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

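The tests of the germ cell and macrophage patterns, of overlapping gene bodies and of the 3' side, and the count of splits for lncRNA neighbours, were chosen after the results were seen. The other counts of splits and the test of group labels by the nearer group were set out before their results. That label test missed its bar, and Hmox1 and the antioxidant list were brought to the labels after their values were seen.

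Whether the counts of calls could arise from any grouping of the libraries was examined with 100 splits of the 10 libraries into 5 and 5, the real one included. Only 1 split, the real one, gave as many changed genes (1232, highest other 808) or protein-coding genes (998, highest other 481). The same held for lncRNAs (116, highest other 24). Chance is argued against for these counts only as far as 1 in 100 splits can show. Every other split mixed VILI and control libraries, and the median of these splits was 0 calls. The count of splits for called lncRNAs beside a called gene (22, highest other 1) decides nothing about their association. It needs called lncRNAs, and 97 splits had none. For the lists chance is not argued against. At least 16 lists were called by camera with a preset correlation in 40 of the 100 splits, and the highest other split called 21. The split with 808 genes set control replicates 1 to 3 and VILI replicates 1 and 2 against the rest, the same parting as the macrophage markers, which points to a structure of the samples beside the groups.

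Control replicate 5 stood apart in germ cell genes, with a sum over 25 genes of 962.5 CPM against 14.18 to 27.9 in the other controls, and with a mean level of 2.595 (centred log2 CPM) over the 4 that were tested. Prm2 reached 176.4 CPM and Prm1 80.31 CPM there, and 352 genes at least 10-fold above every other library made up 0.414% of its counts. Genes shared with motile cilia are argued against, since ciliated markers stood at 0.09 in this library, within the other controls, and so is shallower sequencing, since the other shallow libraries reached at most 19.3 CPM. Of 9 testicular somatic genes only 3 were highest in this library, Insl3, Cyp17a1 and Hsd3b6, at 4.115, 0.5879 and 0.5291 CPM. Clu, another of the 9, stood at 187 CPM or more in every library, where a small addition would not show. All 25 germ cell genes (100%) were highest in control replicate 5, which goes with RNA from testis, as a hypothesis. How such RNA entered was not tested, and the design gives no biological explanation to test.

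Alveolar macrophage markers differed about 10-fold between libraries of one group. Ventilation as the cause is argued against, since 4 libraries were out of place for it. The depth set as the whole cause left 1 library out of place, VILI replicate 3, and 1 library does not decide this. Mislabelled groups were left open by the test set beforehand. Each library was nearer its own group in at least 75% of genes, against a bar of 80%. The antioxidant list argues against mislabelling, at -1.724 to -1.488 in controls and 1.529 to 1.736 in VILI (mean centred log2 CPM). It was picked for this after its values were seen. Hmox1, at 28.7 to 44.5 CPM in controls and 1366 to 2155 CPM in VILI, decides nothing, since its naming required no overlap. Uneven recovery of macrophages from the airspaces was not tested.

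The neighbour association of lncRNAs may in part be technical. Overlapping gene bodies as its whole cause are argued against by the odds ratio of 2.322 without them (95% interval 1.03 to 4.946, Fisher's exact test p = 0.026). Reads running past the 3' end of the partner, as the whole cause, are also argued against. Of 11 pairs that changed together without overlap, 45.5% had the lncRNA on that side. For these 5 pairs such reads remain open. Shared regulation in VILI remains open as a hypothesis, and within replicates 1 to 3 the odds ratio was 1.514 (Fisher's exact test p = 0.183).

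The effect of VILI differed between replicates 1 to 3 and replicates 4 and 5 in 194 genes by an interaction term in edgeR (adjusted p under 0.05), 138 with a lower and 56 with a higher log2 fold change in replicates 4 and 5.

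In 272 groups of 5 libraries, 16 had a library far from the others, and chance alone gives about 1 in 20. The share of the ribosomal RNA gene Rn18s-rs5 was 2.61% in control replicate 1. Ciliated markers stood at 0.598 in control replicate 2 and red cell markers at 1.102 in VILI replicate 3 (mean centred log2 CPM). In VILI replicate 5, Adm2 was at 10.54 CPM, Hmox1 at 2155 CPM and Gm11974 at 9.191 CPM. Cxcl1 was at 3.739 CPM in VILI replicate 1. In control replicate 4, Birc3 was at 44.42 CPM, Socs3 at 39.44 CPM, Osm at 1.601 CPM and Ncr1 at 11.72 CPM. Zbtb16 was at 113.3 CPM in control replicate 3, and Irg1 at 0.443 CPM and Gm4610 at 0.609 CPM in control replicate 5.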

How the results depend on the processing

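The depth-set alternatives, and the neighbour test on every alternative other than distance, direction and overlap, were chosen after seeing the data. Counts of changed genes stayed within 1.5 times under DESeq2 (786 higher, 574 lower), limma-voom (815, 586), RLE scaling (723, 513) and both filters. Leaving out each library gave 639 to 771 higher and 466 to 569 lower genes, and kept 1010 to 1101 of the 1232 called genes. With no fold minimum the counts were 2233 and 1961 genes, 1993 and 1768 protein-coding genes and 105 lower lncRNAs, because the threshold was relaxed. Counting only lncRNAs with a name other than LOC, Gm or Rik left 7 higher and 11 lower, because fewer were counted. Within replicates 4 and 5, 33 lncRNAs were higher and 30 lower, with fewer samples and fewer counts per library, and the cause was not tested. With an estimated correlation 1 list moved up and 0 moved down. The secretory airway list gained a camera call with no filter (adjusted p = 0.0443), with the block (adjusted p = 0.046) and within replicates 4 and 5 (adjusted p = 0.0391), and the alveolar type 1 and type 2 lists within replicates 1 to 3 (adjusted p = 0.00567 and 0.00268). The odds ratio of the neighbour test was 1.514 within replicates 1 to 3, and the cause was not tested. Within replicates 4 and 5 the mean of the alveolar type 1 and type 2 lists, neither called over all libraries, turned to -0.1925 and -0.1633, and the cause was not tested. The alternatives were followed for 134 named genes, all of which but Chil3 had passed an adjusted p under 0.05 in the main fit. None of them changed direction, which that selection on the same libraries made likely. An adjusted p under 0.05 was lost by 8 with limma-voom, 8 with the replicate number as a block and 16 with no filter. It was lost by 17 within replicates 1 to 3, 26 of 132 within replicates 4 and 5, and 10 to 16 with a library left out. With the replicate number as a block, 794 genes were higher and 555 lower, with 651 and 431 protein-coding genes, 52 and 68 lncRNAs, 12 lists up and 5 down and an odds ratio of 2.702. Libraries of the 2 groups were correlated on log2 CPM after each gene's group mean was subtracted, which forces some of the correlations to be negative. On these centred values same-numbered libraries correlated at 0.039 to 0.44, 4 of 5 over 0.1. Of 10 libraries, 5 correlated best with their own number. Control replicates 1 to 3 correlated at 0.285 to 0.44 with VILI replicates 1 and 2, and negatively with VILI replicates 4 and 5. Control replicates 4 and 5 correlated at 0.338 to 0.431 with VILI replicates 4 and 5, and negatively with VILI replicates 1 and 2. This structure crossed the numbers, which were not taken as pairs, and the main fit leaves it out. The median level of lncRNAs was 1.05 CPM, so changes in many of them rest on few counts.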

Other observations

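All lists in this part were chosen after seeing the data. Their camera p-values, adjusted over the lists of this part alone, describe the lists and are no independent test. Genes of stressed or transitional alveolar epithelium, a state described in lung repair, rose in 8 of 13 cases, with 10 adjusted over the list alone. The risen members Krt19, Cldn4, Cdkn1a and Plaur also belong to lists of the main results, so this count is not separate from theirs. Sfn, which encodes 14-3-3 sigma, rose from 8.05 ± 2.74 to 193.9 ± 28.9 CPM and Nupr1 from 54.5 ± 12.2 to 455 ± 179.2 CPM (SD, n = 5; edgeR adjusted p = 4.77e-07 and 2.5e-05). The keratins Krt8 and Krt18 rose by log2 2.02 (SE 0.255) and 2.00 (SE 0.24), at adjusted p-values of 0.000313 and 0.000221. Camera gave adjusted p = 2.4e-09, and adjusted p = 0.0696 with an estimated correlation. Genes activated by p53 rose in 9 of 15 cases, or 10 risen and 1 fallen adjusted over the list alone. Of these, Cdkn1a and Sesn2 rose and also belong to lists of the main results. Pmaip1 rose by log2 1.93 (SE 0.159), Fas by 1.68 (SE 0.159) and Trp53inp1 by 1.62 (SE 0.095), at adjusted p-values of 1.73e-05, 4.25e-05 and 1.31e-06. The p53 list had adjusted p = 3.91e-06 by camera, and adjusted p = 0.0696 with an estimated correlation.

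Genes of conventional dendritic cells fell in 5 of 12 cases, or 7 adjusted over the list alone. Xcr1, a chemokine receptor of cross-presenting dendritic cells, had a log2 fold change of -2.53 (SE 0.334), Batf3 of -1.18 (SE 0.269) and Irf8 of -0.95 (SE 0.11), at edgeR adjusted p-values of 0.0004, 0.00944 and 0.000175. The dendritic cell list had adjusted p = 0.000646 by camera, and adjusted p = 0.31 with an estimated correlation. Camera did not call the lists of cholesterol synthesis (2 risen and 1 fallen of 15), MHC class II presentation (3 fallen of 9), ribosomal proteins (none of 20 changed), testicular germ cells (none of 4 tested) or testicular somatic cells (1 fallen of 6).

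Among genes whose response differed between the depth sets, Akap12, a scaffold protein, had a log2 fold change of 2.07 within replicates 1 to 3 and of 0.19 within replicates 4 and 5 (adjusted p of the interaction 0.0274). Saa3, an acute phase protein, had 0.94 and 4.69 (adjusted p of the interaction 0.0274). Scel had 1.37 and -1.14 (adjusted p of the interaction 0.00238). These genes were chosen after their values were seen. Cyr61, a YAP target, had 1.57 and -0.10, but its interaction did not pass the threshold (adjusted p = 0.075).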
